A study of Mus musculus with 2 samples.

How the data were processed

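Single-barcode RNA of mouse liver was measured in 2 libraries, 1 per group, made with the 10x 3' kit version 3.1 per the labels' protocols. The deposited values are UMI counts per gene and barcode, with no normalization. The matrices name Cell Ranger 6.1.2 per the file headers, while Cell Ranger 6.0.1, Seurat 4.0.3 and the mm10 build are listed per the submitters' processing notes. Both deposited matrices hold the same 32287 features, including EGFP and GFP, and no barcode has under 500 UMIs. Whether doublets were removed, how the tissue was dissociated and whether reads in introns were counted is not given in the sources used here. Groups were taken from the sample labels, and the Bicd2 target, the age of 4 weeks, the dose of 15 mg/kg and the times from the series' design text. Gene coordinates are from a GENCODE annotation of GRCm38, the assembly that mm10 names, matched by gene ID.

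Barcodes were kept with at least 200 genes and at most 25% mitochondrial UMIs. Doublets were treated with Scrublet in scanpy 1.11.5: per library, the highest-scoring barcodes were removed at 0.8% of barcodes per 1000, which took out 62 and 73. Counts were scaled per barcode and logged, 2000 variable genes and 30 principal components were computed with scikit-learn 1.9.0, and a shared-neighbour graph of 15 neighbours was clustered with leidenalg 0.10.2 at resolution 1.0, without integration of the libraries. This gave 17 clusters. Clusters were named from 17 marker sets fixed before the data were examined, where at least 3 markers of a class were raised by 1 log2 unit or more in at least 3% of barcodes. A further requirement, that 40% of the class's markers be raised, was set after seeing the data. It keeps cluster 3 unnamed, which 3 of 11 markers (Sox9, Krt8 and Krt18) would have made cholangiocyte-like and which holds 0.623% and 21.4% of the kept barcodes of the libraries labelled scramble and shBicd2. The 8 clusters with no name are called the main population. Treating them as a population was decided after seeing the data.

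UMIs were summed per library and class in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and divided by the class total to give CPM. Ratios are the library labelled shBicd2 over the library labelled scramble. Intervals are at 95%: exact Poisson for summed counts, exact binomial (Clopper-Pearson) for shares, exact conditional binomial for ratios, and 2000 Poisson draws of the counts for list medians. They cover counting error only, and a count of 0 allows up to 3 counts. No p-value or standard error was computed and no count of changed genes is given, because barcodes are not replicates. Classes with at least 50 barcodes in each library were compared. Log2 ratios had 0.5 count added to each sum. For 31 gene lists fixed before the data were examined, the median log2 ratio over members with at least 10 UMIs was set against 10000 random lists matched in 20 expression bins. This percentile describes these libraries. Each list had home classes fixed in advance. Its use in the main population and over all barcodes, and of immediate early and heat shock genes in monocyte/macrophage-like barcodes, was added after seeing the data. Of the 14 periportal genes 4 are also in another list, as are 4 of the 7 urea cycle genes, 6 of the 22 interferon gamma genes and none of the type I interferon genes.

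Named genes followed a rule fixed before the data were examined: Bicd2, then per class the 10 highest and 10 lowest ratios among genes with at least 50 UMIs, at least 50 CPM in the higher library and an interval bound beyond 1.5-fold. Left out as possible free RNA were genes under 0.1 of their level in the class where they were highest, hepatocyte and erythroid markers outside their class, mitochondrial, ribosomal, hemoglobin, variable immunoglobulin and receptor genes, and genes with clone names. Hepatocyte markers were kept in the main population. Up to 4 members of each list with the most UMIs could be named too. For monocyte/macrophage-like and B cell-like barcodes, genes at less than 2 times their main population level are given only as a range, a restriction chosen after seeing the data. Ngp is among such list members over all barcodes.

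The fold intervals and list percentiles were tested on simulated counts drawn from the real means and library sizes. Both libraries were drawn as independent Poisson counts from shared means, which is the model the intervals assume. The draws hold no difference between animals, preparations or class make-up and no joint change of genes. They therefore check the calculation and do not give error rates for these data. In the main population, with 9257 genes in the step, the interval held the true fold for 95.4% of unchanged genes, 96.0% of 50 genes raised 2-fold 92.0% of 50 raised 4-fold and 90.0% of 50 lowered to 0.5-fold. The size rule took 0 of 9057 unchanged genes, 25 of the 50 raised 2-fold, 39 of the 50 raised 4-fold, 9 of 50 lowered to 0.5-fold and 17 of 50 lowered to 0.25-fold, so it misses most lowered genes at either size. In monocyte/macrophage-like barcodes, with 478 genes in the step, it took 0 of 278 unchanged genes, 26 of 50 raised 2-fold, 50 of 50 raised 4-fold, 10 of 50 lowered to 0.5-fold and 20 of 50 lowered to 0.25-fold. Of 40 unchanged lists drawn in each, 1 in the main population and 3 in monocyte/macrophage-like barcodes lay outside the central 95% of random lists. Alternatives were other limits on mitochondrial share and genes per barcode, no doublet removal, resolutions 0.5 and 2.0, clustering without the response genes, edgeR 4.0.16 TMM factors (R 4.3.3), other totals, 10 CPM added, equal weights per barcode, subtraction of free RNA, other member minimums and thinning to 500 UMIs. Figures were drawn with matplotlib 3.10.9.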

Results

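Transcripts of single barcodes were counted in livers of wild-type C57BL/6J mice, infected at 4 weeks of age with an adeno-associated virus (AAV) carrying a scrambled control (scramble) or a short hairpin against Bicd2 (shBicd2). Bicd2 encodes an adaptor that links cargo to the dynein motor. After 3 weeks the mice received concanavalin A, a lectin that activates T cells and causes acute hepatitis, at 15 mg/kg into a vein, and livers were taken 6 hours later. Each group held 1 library. The library labelled scramble had 2805 barcodes and 5086306 UMIs (unique molecular identifiers), and the library labelled shBicd2 had 3038 barcodes and 5624055 UMIs. After filtering, 2729 and 2941 barcodes were kept, with medians of 1502 and 1500 UMIs. With 1 library per group no difference has a replicate check, no test between groups was possible, and every interval covers counting error only.

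Bicd2 RNA was not lower in the library labelled shBicd2. Bicd2 (ENSMUSG00000037933, protein coding, GRCm38 chromosome 13, 49341585 to 49387026, plus strand) had 77 UMIs in the library labelled scramble, or 15.7 CPM (95% Poisson interval 12.4 to 19.6). It had 106 UMIs in the library labelled shBicd2, or 19.5 CPM (16.0 to 23.6). The ratio was 1.24 (0.919 to 1.69) over all kept barcodes and 1.56 (1.11 to 2.21) in the main population described next. Barcodes with a Bicd2 UMI made up 2.64% (2.07% to 3.31%) and 3.37% (2.74% to 4.08%), and 1.47% and 2.24% after each barcode was thinned to 1000 UMIs, which left out 752 and 847 shallower barcodes. In B cell-like barcodes Bicd2 had 8 and 0 UMIs, and a count of 0 there allows up to 49.5 CPM. Since the targeted gene was not shown to be lower, every direction that follows compares the library labelled shBicd2 with the library labelled scramble and not a measured loss of Bicd2.

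EGFP, a reporter sequence added to the reference, differed far more than Bicd2. It had 334 UMIs, or 68.1 CPM (61.0 to 75.8), in the library labelled scramble and 4842 UMIs, or 892 CPM (867 to 917), in the library labelled shBicd2, a ratio of 13.1 (11.7 to 14.7). The share of barcodes with an EGFP UMI was 6.08% (5.22% to 7.05%) against 27.4% (25.8% to 29.0%), and 4.91% against 23.8% after thinning. In B cell-like barcodes, with medians of 995 and 869 UMIs, that share was 3.88% and 10.9%, a level that free RNA can give. A further GFP feature had 0 UMIs in both libraries. The labels do not say which vector carries EGFP.

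The next comparison asks which cell classes the livers yielded. Both libraries were led by barcodes with hepatocyte enzyme RNA and little mitochondrial RNA, called here the main population. They made up 77.4% (75.8% to 78.9%) and 76.8% (75.2% to 78.3%) of kept barcodes. B cell-like barcodes had a lower share in the library labelled shBicd2, 1.87% (1.41% to 2.43%) against 3.77% (3.09% to 4.56%), a ratio of 0.495 (0.350 to 0.694). Endothelial-like barcodes were also fewer, 1.02% against 1.76%, a ratio of 0.580 (0.355 to 0.934). Stellate/fibroblast-like barcodes had a higher share, 2.55% against 1.58%, a ratio of 1.62 (1.10 to 2.41). Neutrophil-like barcodes, led by S100a8, S100a9, Ngp and Mmp8, numbered 42 in the library labelled shBicd2 and 1 in the library labelled scramble, shares of 1.43% and 0.0366%. That ratio of 39.0 (6.62 to 1576) lay between 1.30 and 41.7 under other settings. The cluster raised 15 of 16 neutrophil markers, 8 of them among its 10 leading genes. These markers give the cluster its name and do not bear on its split between the libraries. Why the cluster came almost wholly from 1 library was not tested.

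Monocyte/macrophage-like barcodes had equal shares, 2.67% (2.10% to 3.35%) and 2.69% (2.13% to 3.34%). Hepatocyte-like barcodes, which carried more mitochondrial RNA than the main population, numbered 327 and 381, a ratio of shares of 1.08 (0.930 to 1.26) that ran from 0.497 to 8.29 under other filters. Erythroid-like barcodes numbered 7 and 15, and mesothelial-like barcodes 15 and 6. No cluster took the name of a T cell or natural killer cell. But the B cell-like cluster, with 9 of 12 B cell markers raised, also raised 4 of 15 natural killer and 3 of 15 T cell markers and may be mixed. Its share need not be that of B cells. Among immune barcodes alone (177 and 176), B cell-like barcodes made up 58.2% (50.6% to 65.5%) in the library labelled scramble and 31.2% (24.5% to 38.7%) in the library labelled shBicd2.

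**Figure D1:**
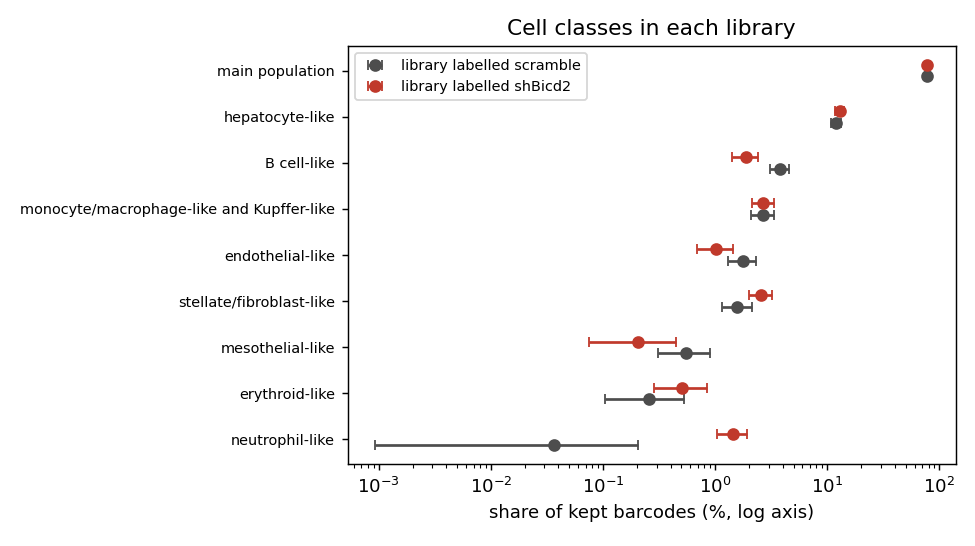
Share of kept barcodes in each cell class (percent, log axis) for both libraries, with 95% exact binomial intervals. The main population stands at 77.4% and 76.8%, B cell-like barcodes at 3.77% and 1.87%, and neutrophil-like barcodes at 0.0366% and 1.43% in the libraries labelled scramble and shBicd2.

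The main population also shows how the barcodes were made up. Median mitochondrial shares there were 0.151% and 0.274% in the libraries labelled scramble and shBicd2. The nuclear long noncoding RNA Malat1 stood at 36810 and 26638 CPM, and Neat1, another, at 68620 and 48698 CPM. The labels name single cells, yet nuclei give such a profile too, so every CPM value, that of Bicd2 included, may describe nuclear RNA. The libraries barely mixed: clusters 2, 4, 7 and 9 held 95.7% of the main population of the library labelled scramble, and clusters 1, 3, 6 and 14 held 93.4% of that of the library labelled shBicd2. Free RNA may have been abundant, since the share of hepatocyte marker UMIs in B cell-like barcodes, a cluster that may be mixed, was 0.719 and 0.857 times that of the whole library. In those barcodes of the library labelled shBicd2, EGFP and Hspa1b lay far under such a share. They stood at 148 and 33.0 CPM, against 892 and 684 CPM over all kept barcodes. Scaling with TMM factors would lower every log2 ratio of the main population by 0.16.

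Among the 10 highest ratios of the main population under the naming rule, library labelled shBicd2 over library labelled scramble, were genes of lipid storage, oxidation and stress, beside EGFP and noncoding RNAs. G0s2, an inhibitor of triglyceride breakdown (chromosome 1, 193272161 to 193273217), had 1.70 CPM in the library labelled scramble and 63.9 CPM in the library labelled shBicd2, a ratio of 37.5 (18.0 to 94.0). Plin2, which coats lipid droplets, stood at 82.8 and 634 CPM, a ratio of 7.65 (6.84 to 8.59). The oxidases Aox1 and Fmo1 had ratios of 11.9 (7.79 to 19.1) and 9.60 (6.55 to 14.6). Srxn1, which repairs oxidised peroxiredoxins, had 7.91 (5.62 to 11.4), the small heat shock protein Hspb1 7.97 (5.85 to 11.1) and the stress-responsive Ndrg1 9.66 (6.35 to 15.4). Rian and Mirg, noncoding RNAs of 1 imprinted locus, had ratios of 11.9 (8.91 to 16.2) and 13.6 (8.43 to 23.3). Both were leading genes of cluster 14, which held 8 and 70 barcodes of the libraries labelled scramble and shBicd2. Ratios of the main population may therefore come from its make-up and need not hold across its barcodes.

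The lowest ratios of the main population under that rule belonged to a receptor, liver enzymes and signalling genes. Nrp1, a co-receptor for semaphorins and VEGF (chromosome 8, 128358604 to 128503363), stood at 283 CPM in the library labelled scramble and 33.2 CPM in the library labelled shBicd2, a ratio of 0.117 (0.0984 to 0.139). Cyp2c70, a bile acid hydroxylase (chromosome 19, 40153353 to 40187333), stood at 1047 and 131 CPM, a ratio of 0.125 (0.115 to 0.136). Ratios were 0.172 for Cyp21a1, 0.189 for the uridine phosphorylase Upp2, 0.218 for D10Wsu102e, 0.236 for Socs2, which dampens growth hormone signalling, 0.240 for Palmd and 0.264 for the hepatocyte transcription factor Onecut1. The interferon-induced genes Ifi44 and Trim12c had ratios of 0.213 (0.179 to 0.252) and 0.261 (0.206 to 0.329). Trim12c, Cyp21a1 and Cyp2c70 have close paralogs, so reads may be shared. Nrp1 and Cyp2c70 were among the leading genes of cluster 7, which held 304 and 4 barcodes of the libraries labelled scramble and shBicd2. Here too the make-up of the main population may give part of the ratios, which was not tested.

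**Figure D2:**
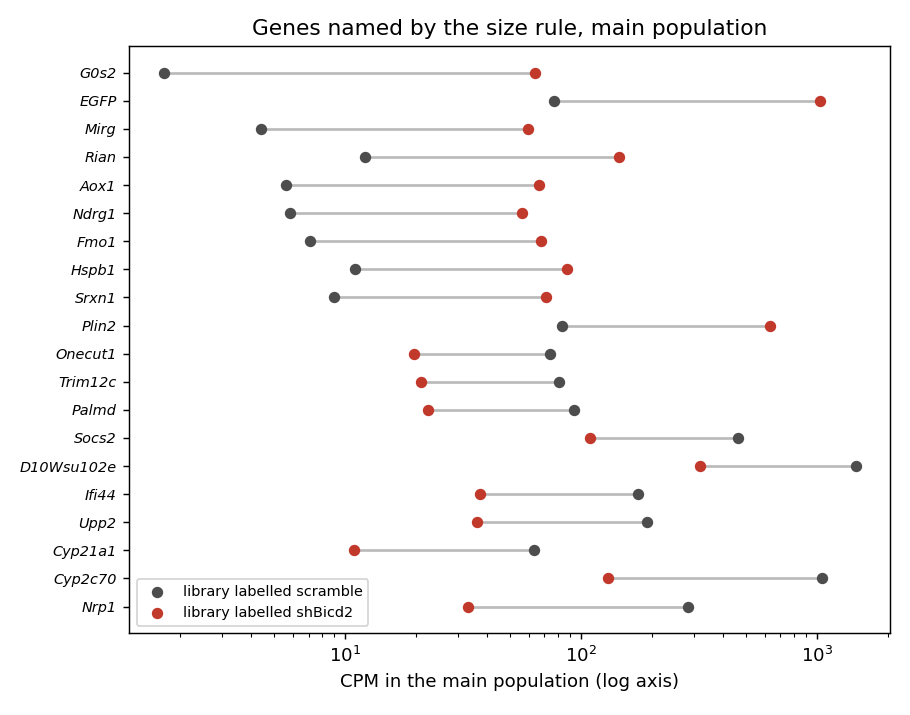
CPM (log axis) in the main population of each library for the 10 highest and 10 lowest ratios under the naming rule, without error bars. G0s2 runs from 1.70 CPM in the library labelled scramble to 63.9 CPM in the library labelled shBicd2, and Nrp1 from 283 to 33.2 CPM.

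Urea cycle genes, and most measured periportal genes, were higher in the main population of the library labelled shBicd2. All 7 urea cycle genes were higher, with a median log2 ratio of 0.70 (0.63 to 0.99), at percentile 98.7 of 10000 random lists matched on expression. Asl, the argininosuccinate lyase, stood at 135 and 549 CPM, and Cps1, which makes carbamoyl phosphate, at 187 and 545 CPM. Of 13 measured periportal genes, 9 were higher, with a median of 0.95 (0.66 to 1.04, percentile 99.99), while Pck1 and Sds, enzymes of gluconeogenesis and serine breakdown, had ratios of 0.637 (0.614 to 0.661) and 0.379 (0.356 to 0.404). Cps1, Asl and Ass1 are in both the urea cycle and the periportal list, so these are not separate results. Of 15 lipid genes 11 were higher, median 0.45 (0.40 to 0.51, percentile 98.7), and of 16 xenobiotic genes 9, median 0.49 (0.19 to 0.62, percentile 98.6). Bile acid genes had a median of -0.18 (-0.46 to -0.10, percentile 6.5), with Cyp27a1 at a ratio of 0.460 (0.420 to 0.503). Pericentral genes went both ways, median 0.20 (-0.29 to 0.59, percentile 59.7), with Glul at 0.422 (0.382 to 0.465) and Oat at 1.87 (1.61 to 2.18). Glul was a leading gene of cluster 7 and Oat of cluster 14, which the libraries shared unevenly. Mitochondrially encoded genes had a median of 0.72 (0.64 to 0.85, percentile 99.8). Subtracting free RNA gave medians of 0.26 for urea cycle and 0.12 for lipid genes and turned the pericentral median negative. That step takes off the mean profile of the whole library, which includes the main population itself, at 0.719 and 0.857 of the UMIs. Here and below, it cannot tell free RNA from a population's own RNA. In barcodes with no mitochondrial UMI the xenobiotic median was -0.27 and that of 5 pericentral genes -2.31 (-2.89 to -1.21).

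Type I interferon response genes were lower in the library labelled shBicd2. All 17 measured type I interferon response genes had a lower level in its main population, with a median log2 ratio of -1.02 (-1.13 to -0.87), below all 10000 random lists (percentile 0). Usp18, a brake on interferon receptor signalling, stood at 287 and 104 CPM, Rsad2, an antiviral enzyme, at 253 and 134 CPM, and Isg15, a ubiquitin-like modifier, at 241 and 133 CPM. Zbp1, a nucleic acid sensor, had a ratio of 0.949 (0.869 to 1.04). Interferon gamma response genes were split, with 8 of 20 higher and a median of -0.12 (-0.18 to -0.05, percentile 18.9), Irf1 at a ratio of 1.55 (1.49 to 1.61) and Cxcl10 at 0.843 (0.819 to 0.868). The type I median was -0.42 in the 188 and 63 barcodes with no mitochondrial UMI. Cluster 4 of the main population was led by Ifit2, Ifit1 and Rsad2. It held 541 and 81 barcodes of the libraries labelled scramble and shBicd2, or 19.8% and 2.75% of those kept. The lower median may thus come in part from this cluster and need not be even across the main population, which was not tested.

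Immediate early, heat shock and hypoxia genes of the main population were higher in the library labelled shBicd2. All 15 immediate early and heat shock genes were higher, with a median log2 ratio of 0.79 (0.69 to 1.03, percentile 100). Hsp90aa1, a chaperone, stood at 249 and 939 CPM, and Jund, a subunit of AP-1, at 899 and 2054 CPM. Without the barcodes carrying EGFP that median was 0.14. All 9 measured oxidative stress and metallothionein genes were higher, median 0.53 (0.44 to 0.72, percentile 97.1), with Gclc, which limits glutathione synthesis, at a ratio of 3.21 (2.90 to 3.57). Of 14 hypoxia and glycolysis genes 11 were higher, median 0.54 (0.44 to 0.64, percentile 99.4). Endoplasmic reticulum stress genes had 12 of 15 higher, median 0.22 (0.14 to 0.31, percentile 80.7), and MHC class I genes 9 of 11, median 0.21 (0.11 to 0.29, percentile 82.9), both within the range of random lists, and both medians turned negative when free RNA was subtracted. TNF/NF-kB response genes had 13 of 18 higher, median 0.21 (0.13 to 0.35, percentile 85.1), or 0.05 with TMM factors. Myeloid cytokine and chemokine genes had 9 of 14 higher and a median of 0.23 (-0.10 to 0.95, percentile 54), with Ccl2, a monocyte chemokine, at 163 and 652 CPM and Cxcl2, a neutrophil chemokine, at 646 and 1285 CPM. Acute phase genes had 7 of 18 higher, median -0.13 (-0.16 to -0.11, percentile 20.3), with Saa1 at a ratio of 0.740 (0.731 to 0.750), and -1.10 with free RNA subtracted. Cell death and p53 genes (median 0.18, -0.04 to 0.37, percentile 72.4) and cytokine and death receptors (0.07, -0.07 to 0.23, percentile 46.4) had intervals that included 0, with Cflar at a ratio of 0.603 (0.566 to 0.643) and Mdm2 at 2.18 (2.02 to 2.35). Dynein, dynactin and BICD family genes had a median of 0.19 (0.06 to 0.27, percentile 76.4), or -0.04 with free RNA subtracted.

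**Figure D3:**
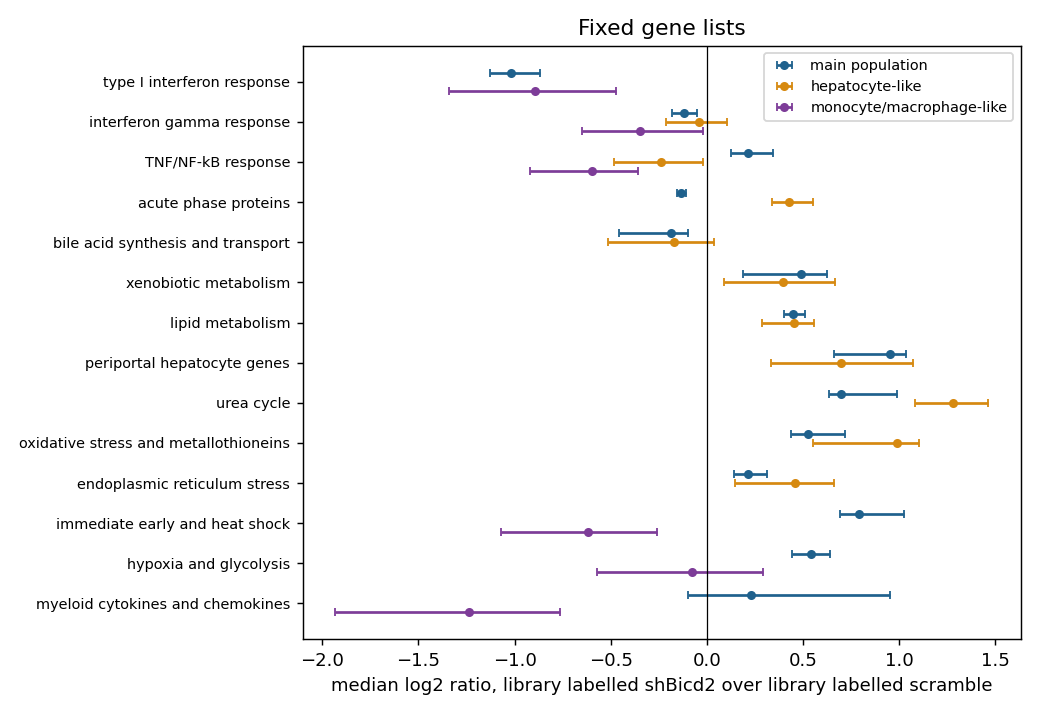
Median log2 ratio (library labelled shBicd2 over library labelled scramble) of 14 gene lists in 3 populations, with bars for 95% counting intervals and a line at 0. Type I interferon genes stand at -1.02 and urea cycle genes at 0.70 in the main population, while endoplasmic reticulum stress medians, and the lipid and xenobiotic medians of hepatocyte-like barcodes, turn negative with free RNA subtracted and the xenobiotic median of the main population in barcodes with no mitochondrial UMI.

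In hepatocyte-like barcodes (327 and 381), 5 of the 10 highest ratios under the naming rule, library labelled shBicd2 over library labelled scramble, belonged to enzymes of cholesterol synthesis, a grouping made after seeing the genes and not tested in this class. These, Nsdhl, Hmgcs1, Fdps, Fdft1 and Hsd17b7, had ratios of 16.6 (5.38 to 83.1), 10.0 (6.16 to 17.2), 7.74 (5.05 to 12.4), 7.25 (3.29 to 18.9) and 5.46 (2.76 to 12.0). EGFP had 9.72, with a lower bound of 4.48, Plin2 8.65 (6.17 to 12.4), Krt8, a keratin, 5.78 (4.38 to 7.75) and Ftcd, an enzyme of histidine breakdown, 5.49 (3.78 to 8.20). Nrp1 had the lowest ratio, 0.0840 (0.0392 to 0.160), and Upp2, Smad5, Trim12a, Socs2 and D10Wsu102e had ratios of 0.133, 0.137, 0.150, 0.187 and 0.197. The 10 highest and 10 lowest ratios under that rule were of genes at 0.148 to 1.78 times their main population level, where free RNA can supply them, and for Nrp1, Upp2 and Socs2 the main population had ratios of 0.117, 0.189 and 0.236. All 7 urea cycle genes were higher, median 1.28 (1.08 to 1.46, percentile 99.99). Acute phase genes had 14 of 18 higher, median 0.43 (0.34 to 0.55, percentile 97.2), with haptoglobin (Hp) at a ratio of 1.81 (1.72 to 1.90), and TNF/NF-kB genes 10 of 17 lower, median -0.24 (-0.49 to -0.02, percentile 17.6). Cluster 5 held 290 of the 327 barcodes of the library labelled scramble, and clusters 5 and 8 held 212 and 169 of the others. Cluster 8 had a median of 911 UMIs and 7.38% mitochondrial UMIs and also raised 5 of 10 erythroid, 4 of 16 neutrophil, 3 of 16 endothelial and 3 of 14 monocyte/macrophage markers, so differences in this class may come from its make-up.

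Monocyte/macrophage-like barcodes (73 and 79) had lower cytokine and type I interferon genes in the library labelled shBicd2, and median mitochondrial shares of 0.275% and 1.58%. Of 10 measured myeloid cytokine and chemokine genes 9 were lower, with a median log2 ratio of -1.24 (-1.93 to -0.76), below all 10000 random lists (percentile 0), or -0.60 with only members of at least 50 UMIs. Ccl4, a chemokine, stood at 1607 and 252 CPM, a ratio of 0.157 (0.0915 to 0.255). Tnip3, an inhibitor of NF-kB, had a ratio of 0.117 (0.0361 to 0.293) and Spic, a transcription factor of iron-recycling macrophages, 0.202 (0.0915 to 0.401). The chaperone gene Hspa1b had 0.232 (0.157 to 0.334), and Hsph1, another, stood at 924 and 146 CPM from 73 and 11 UMIs. Tiparp and Rapgef2 had ratios of 0.204 (0.106 to 0.365) and 0.213 (0.111 to 0.382). Immediate early and heat shock genes, examined in this class only after Hspa1b and Hsph1 had been seen to be low, had 9 of 12 lower and a median of -0.62 (-1.07 to -0.26, percentile 3.82). Of 10 type I interferon genes 8 were lower, median -0.89 (-1.34 to -0.47, percentile 0.3), of 15 TNF/NF-kB genes 12, median -0.60 (-0.92 to -0.36, percentile 2.3), and of 21 interferon gamma genes 14, median -0.35 (-0.65 to -0.02, percentile 13.8). Free RNA can supply part of these lists, since in the library labelled scramble Cxcl1, Zfp36 and Cxcl10 stood at 1012, 1581 and 772 CPM here and at 2778, 2153 and 2284 CPM in the main population. Genes higher in the library labelled shBicd2 were Slfn4, an interferon-regulated myeloid gene, at 3.48 (1.96 to 6.52), the protease gene Ctsc at 3.43 (1.89 to 6.58), Cd74, the MHC class II invariant chain, at 3.35 (2.03 to 5.76) and the inhibitory receptor gene Pirb at 2.90 (1.89 to 4.57). MHC class II genes as a list went both ways, median -0.17 (-0.85 to 1.17, percentile 30.5). Hypoxia and glycolysis genes, for which this was a home class, had 6 of 12 higher, median -0.08 (-0.57 to 0.29, percentile 47.2). Of 5 measured alternative activation and repair macrophage genes 3 were higher and 2 lower, median 0.82 (0.07 to 1.40, percentile 97.6). The other genes among the 10 highest and 10 lowest ratios under the naming rule, including major urinary protein genes, Lcn2, Orm1 and Cyp2c70, lay at 0.467 to 1.64 times their level in the main population, where free RNA can supply them. Clustering at resolution 2.0 parted this class into Kupffer-like barcodes (63 and 47) and monocyte/macrophage-like barcodes (10 and 35). The make-up of the class thus differed between the libraries, and differences in its genes may come from that.

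In B cell-like barcodes (103 and 55) Ighm, the immunoglobulin heavy chain mu gene, stood highest over its main population level among the 10 highest and 10 lowest ratios under the naming rule. It stood at 170 CPM in the library labelled scramble and 1303 CPM in the library labelled shBicd2, a ratio of 7.66 (4.80 to 12.7). These levels came from 24 UMIs in 103 barcodes and 79 UMIs in 55. The make-up of this cluster, which may be mixed, may therefore differ between the libraries. Gclc had a ratio of 6.30 (3.54 to 11.7) at 2.07 times its level in the main population. The others of these, from Mup11 to Cyp2c70 and Cxcl10, lay at 0.490 to 1.39 times that level. MHC class II genes had a median log2 ratio of -0.13 (-1.26 to 0.71, percentile 36.9). Over all kept barcodes, neutrophil activation genes had 12 of 13 higher, median 1.10 (0.73 to 1.69, percentile 99.99), with Ngp at 4.08 and 33.9 CPM. Ngp, Mmp8, Ltf and Mmp9, of that list, were leading genes of the neutrophil-like cluster of 1 and 42 barcodes. This median may therefore come from the share of that cluster. In the main population that list had 11 of 12 higher, median 1.08 (0.60 to 1.57, percentile 99.9), or -0.31 with free RNA subtracted. Proliferation genes had 9 of 12 higher, median 0.56 (0.22 to 0.94), which is within the random lists (percentile 86.2), and 0.06 (-0.36 to 0.80, percentile 22.4) in the main population. Mki67 and Top2a, of that list, were leading genes of the erythroid-like cluster of 7 and 15 barcodes. Lymphocyte activation genes (median 0.00, -0.45 to 0.40, percentile 16.5) and cytotoxic effector genes (0.16, -0.36 to 0.66, percentile 38.0) had intervals that included 0, with Gzmb, a cytotoxic granule protease, at 5.10 and 10.1 CPM. So had regulatory T cell and checkpoint genes (-0.46, -0.97 to 0.18, percentile 3.6), fibrogenic genes (0.36, -0.23 to 0.94, percentile 55.4) and endothelial activation genes (0.01, -0.03 to 0.06, percentile 35.9).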

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

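The Bicd2 tests of low counts and exchanged labels, the TMM test and the subsets of barcodes were chosen after the results were seen, and only for the subsets and the split by EGFP were bounds fixed before the tested values were computed. Gene lists whose medians had opposite signs, each with a counting interval excluding 0, are given here as differences between populations that were not tested. The TNF/NF-kB list differed by -0.45 on the log2 scale between hepatocyte-like barcodes and the main population, and by -0.81 between monocyte/macrophage-like barcodes and the main population. The acute phase list was 0.56 higher in hepatocyte-like barcodes than in the main population. The immediate early and heat shock list was -1.41 in monocyte/macrophage-like barcodes relative to the main population (-0.62 against 0.79), a class in which it was examined only after 2 of its genes had been seen to be low.

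Bicd2 was not lower in the library labelled shBicd2. Over all kept barcodes, low counts do not account for a missed fall to 0.5-fold, since the lower bound of that ratio was 0.919. In hepatocyte-like barcodes Bicd2 had 7 and 6 UMIs, a ratio of 0.821 (0.228 to 2.85). That interval includes 0.5, so low counts leave such a fall open in that class. A knockdown limited to barcodes that carry EGFP remains open: within the library labelled shBicd2, main population barcodes with an EGFP UMI had 0.691 (0.433 to 1.08) times the Bicd2 CPM of those without, from 30 and 66 UMIs, an interval that includes both 1 and a clear fall. These EGFP barcodes had 16.4 CPM, and the main population of the library labelled scramble had 13.4 CPM. The same split within the library labelled scramble had the same direction, 0.342 (0.0404 to 1.30) from 2 and 53 UMIs. Exchanged labels cannot be told apart from a failed or late-acting hairpin, because the ratio of 1.56 in the main population has only these libraries behind it, and loss of the protein or of cytoplasmic RNA was not tested.

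Type I interferon genes were lower in the library labelled shBicd2. Barcodes carrying EGFP do not hold the difference, since the median log2 ratio in the main population was -1.29 (-1.52 to -1.16) without them. Heat shock barcodes do not hold it either, with a median of -1.20 (-1.37 to -1.04) without them, and TMM scaling gave -1.11 over all barcodes. Whether cluster 4 holds the difference was not tested. That cluster was led by Ifit2, Ifit1 and Rsad2 and had 541 and 81 barcodes in the libraries labelled scramble and shBicd2. An effect of the vector, of Bicd2 or of the stage of hepatitis in each animal, and any difference in library preparation, stay open, because each group has 1 library and these cannot be separated from it.

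Urea cycle and periportal genes, lists that share Cps1, Asl and Ass1, were higher in the library labelled shBicd2, together with mitochondrial RNA. Whether more cytoplasmic RNA per barcode is the cause cannot be decided here. Among 188 and 63 main population barcodes with no mitochondrial UMI the medians of 6 and 10 measured members were 1.32 (0.95 to 1.82) and 1.36 (0.96 to 1.78). But at the main population's median mitochondrial shares of 0.151% and 0.274%, few such UMIs are to be found per barcode. A count of 0 therefore need not mean less cytoplasmic RNA. Barcodes carrying EGFP do not hold the urea cycle difference, with a median of 0.99 (0.91 to 1.10) without them. Differences between the animals, the vectors and the library preparations stay open and untested.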

How the results depend on the processing

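The subsets of barcodes without an EGFP UMI, without a heat shock UMI and with no mitochondrial UMI were chosen after the data were seen. No paired analysis was possible because each group has 1 library and the labels give no replicate numbers. Of the values that answer a comparison, 200 stayed within their counting interval, 61 moved beyond it and 1 reversed; of the others 1565, 184 and 16 did. Except where stated, the cause was not tested. Subtraction of free RNA takes the mean profile of each library off at 0.719 and 0.857 of a class's UMIs. That profile includes the main population itself. The share does not hold for every gene. In B cell-like barcodes of the library labelled shBicd2, EGFP stood at 148 CPM (67.9 to 282) and Hspa1b at 33.0 CPM (3.99 to 119). Over all kept barcodes of that library they stood at 892 and 684 CPM, so a share of 0.857 was too high for both.

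The ratio of hepatocyte-like shares was 8.29 with at most 10% mitochondrial UMIs, 0.727 with no such limit, 0.497 with at least 500 genes, 0.646 with no doublet removal and 0.692 at resolution 0.5. The neutrophil-like ratio was 3.50 with at most 10% mitochondrial UMIs, 1.30 at resolution 0.5, 5.01 at resolution 2.0 and 4.45 clustered without response genes. The main population's ratio was 1.07 with at least 500 genes and 1.06 with no doublet removal. Other values are log2. In the main population, acute phase medians were -0.11 with no mitochondrial limit, -0.11 with at least 500 genes, -0.11 with no doublet removal and -0.11 at resolution 0.5, and lipid medians 0.36 with at most 10% mitochondrial UMIs, 0.39 at resolution 2.0 and 0.40 clustered without response genes.

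With TMM factors EGFP was 3.55 over all barcodes and 3.57 in the main population, and medians in the main population were 0.050 for TNF/NF-kB, -0.30 for acute phase, 0.032 for dynein, -0.28 for interferon gamma, 0.29 for lipid, -1.18 for type I interferon and 0.54 for urea cycle genes. Over all barcodes they were -0.053 for TNF/NF-kB and -0.043 for dynein genes, both reversed, 0.51 for immediate early and heat shock and -1.11 for type I interferon genes. With 10 CPM added, EGFP was 3.53 over all barcodes, type I interferon genes -0.79 there and -0.84 in the main population, and periportal genes 0.64. With barcodes weighted equally, acute phase genes over all barcodes (0.046) and mitochondrial genes in hepatocyte-like barcodes (-0.20) reversed, heat shock genes were 0.51 over all barcodes and lipid genes 0.52 in the main population.

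With free RNA subtracted the main population had Bicd2 at 1.84, EGFP 4.09, TNF/NF-kB 0.50, acute phase -1.10, interferon gamma -0.37, lipid 0.12, type I interferon -1.42 and urea cycle 0.26, and reversed medians for dynein (-0.042), MHC class I (-0.26), endoplasmic reticulum stress (-0.051) and neutrophil genes (-0.31). In hepatocyte-like barcodes endoplasmic reticulum stress (-0.050), lipid (-0.24), mitochondrial (-0.35) and xenobiotic (-0.077) medians reversed. Myeloid cytokine genes in monocyte/macrophage-like barcodes were -2.12, and -0.60 with members of at least 50 UMIs.

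In the main population without EGFP barcodes, medians were 0.087 for TNF/NF-kB, -0.10 for acute phase, 0.30 for dynein, -0.19 for interferon gamma, 0.58 for lipid, -1.29 for type I interferon and 0.99 for urea cycle genes, and endothelial activation (-0.082) and sex-linked genes (0.026) reversed. Without heat shock barcodes they were -0.062 for acute phase, 0.57 for lipid and -1.20 for type I interferon genes. Among barcodes with no mitochondrial UMI, which are few, they were 0.0013 for TNF/NF-kB, -0.30 for interferon gamma, 0.36 for lipid, 1.36 for periportal, -0.42 for type I interferon and 1.32 for urea cycle genes, and MHC class I (-0.22), endothelial activation (-0.26) and xenobiotic genes (-0.27) reversed. Pericentral genes and cytokine and death receptors, whose intervals included 0 before, were -2.31 and -0.12 there.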

Other observations

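The cholesterol gene list, the split by EGFP and the subsets below were chosen after the data were seen, and the bound for the cholesterol test was set before its value was computed. Of the genes first tested, 2 were moved out only after the test's first result was seen, because their values had been examined before, which leaves 15. Genes of cholesterol synthesis were higher in the main population of the library labelled shBicd2. Fdps, Mvk and Pmvk, enzymes of the mevalonate pathway, had ratios of 5.36 (4.61 to 6.24), 6.87 (3.54 to 14.9) and 4.62 (3.47 to 6.24). Whether more of the pathway was higher was tested on 15 of its genes outside the 8 whose values had been seen. All 15 were higher, with a median log2 ratio of 1.05 (0.86 to 1.19) at percentile 100 of matched random lists. That median was 1.26 without barcodes carrying EGFP, 1.09 without heat shock barcodes, 0.93 in barcodes with no mitochondrial UMI and 0.89 with TMM factors. Subtraction of free RNA was not run on these genes. They come from the same barcodes as the 8, and genes of 1 pathway can vary together while random lists do not. The test thus shows how far the difference reached in these libraries and is not independent support for it. A lipid response of hepatocytes may underlie this, but the animals and libraries differ along with the vector.

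Barcodes carrying an EGFP UMI had a profile of their own in both libraries. Within the main population of the library labelled shBicd2, 721 barcodes with an EGFP UMI and 1537 without differed by a median log2 ratio of 1.75 for immediate early and heat shock genes, 0.82 for type I interferon genes and -0.86 for urea cycle genes. In the library labelled scramble, 152 and 1960 such barcodes differed by 1.33, 0.37 and -0.34. Barcodes with 3 or more EGFP UMIs (322 and 37) differed from those without by 2.14, 0.46 and -1.50 in the library labelled shBicd2 and by 1.46, 0.17 and -0.23 in the library labelled scramble. EGFP reached 2456 CPM in cluster 3, whose leading genes include Hspa1a, Hspa1b, Hspb1 and linker histone genes. A heat shock state tied to the vector may explain part of the difference between the libraries, since the heat shock median fell from 0.79 to 0.14 without these barcodes. They were also deeper, with medians of 2178 and 1541 UMIs with and without EGFP in the library labelled shBicd2, so an EGFP UMI was easier to find in them.

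The macrophage class was parted into Kupffer-like and monocyte/macrophage-like barcodes in 3 of the clustering settings. Kupffer-like barcodes numbered 63 and 45 with no mitochondrial limit and 65 and 47 with no doublet removal, and monocyte/macrophage-like barcodes 9 and 42, then 10 and 34, in the libraries labelled scramble and shBicd2. Ddx3y, a Y-linked gene, stood at 201 and 172 CPM, a ratio of 0.855 (0.781 to 0.936), Uty, another, had a ratio of 0.834 (0.757 to 0.920), and Xist stood at 2.04 and 2.21 CPM. Endothelial angiocrine and flow genes had 7 of 7 measured members higher over all barcodes, with a median of 0.83 (0.59 to 1.73), within the random lists (percentile 92.9), and 0.36 (-0.37 to 1.08) in the main population. Hgf, of that list, had a ratio of 3.44 (1.96 to 6.40) and was a leading gene of the stellate/fibroblast-like cluster.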
